A study of Mus musculus with 22 samples.

How the data were processed

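Gene expression was measured on 22 Agilent mouse arrays with 1 array per group, so no group was replicated. A time course followed primordial germ cells (PGCs) from embryos at E11.5 through day 1 with bFGF, days 2, 3 and 6 with bFGF, a MEK and a GSK inhibitor (2i) and A83-01, and day 10, to an embryonic germ cell (EGC) line. An embryonic stem cell (ESC) line stood beside them. Further PGC cultures were taken at day 2 with bFGF alone or with the MEK inhibitor PD325901, the GSK inhibitor CHIR99021, A83-01, which inhibits activin and TGF-beta receptors, 4-hydroxytamoxifen (4OHT), used to activate AKT, or 2i, A83-01 and 4OHT together. The third part held EBRTcH3 ESCs, parental or with forced expression of GFP, Prdm14, Vasa, Nanos2, Nanos3, Dnd or Blimp-1. Per the labels, PGC cultures, ESCs and EGCs were sorted on SSEA-1 and cells carrying constructs on GFP. The arrays lay on 10 slides, read from the file headers.

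Per the file headers, the authors scanned each array in 1 colour and processed it with Agilent Feature Extraction 10.7.3.1, with the design annotated on mm9. The deposited spot values are intensities, background-subtracted and detrended within the array and not normalized between arrays. The deposited value table of the series also holds intensities and was used only as an alternative. No column lacked a mapped sample, and no group was left out.

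Outlier spots were left out, repeat spots were averaged, and log2 intensity minus the log2 of the array's 75th percentile is called the level below. The 41174 probes were named by RefSeq accession (27584), symbol (5493) or synonym (635), and 7462 kept the name in the file. This gave 27352 genes, of which 9040 had several probes, and the probe with the highest mean level over the 22 arrays stood for the gene. Genes well above background, by the scanner's call, on at least 1 array of a fit were tested. Precision is limited by signal over background: the percentage of probes well above background was 44.3 on the array with 2i, A83-01 and 4OHT, 48.8 on parental EBRTcH3, 51.2 on uncultured PGCs and 64.7 on the EGC line, and the 75th percentiles of those arrays were at intensities of 124, 195, 206 and 460.

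Models were fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The time trend was the slope on log2(day + 1) over 6 arrays. Uncultured PGCs were tested against 3 lines (ESC, EGC and parental EBRTcH3), with the spread taken from the lines. The 7 day 2 arrays were fitted with 4 additive terms (MEK inhibitor, GSK inhibitor, A83-01 and 4OHT), which leaves 2 residual degrees of freedom, and departures from additivity count as error. Each construct was tested against the other arrays of its slide, with slide as a fixed block over the 8 EBRTcH3 arrays and 4 residual degrees of freedom. A lone array is assumed to vary like the others of its fit. The p-values therefore measure only the spread between these arrays, not between repeated cultures, and precision is limited by the number of arrays. The EGC and ESC lines, and all differences between 2 arrays, have no test. Pearson and Spearman correlations of effects run across genes, which are not independent replicates.

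Where a gene was not well above background on 1 side, that side was set to the lowest level called well above background on its array, and the difference is given as "at least N-fold". For named genes of PGCs and constructs, each dim array among several on the lower side was treated the same way. For 31 gene lists the median log2 difference was placed among 10000 random lists of the same size matched on mean level in 20 bins. A list below percentile 2.5 or above percentile 97.5 is called outside the range of random lists. This describes the arrays and is not a test of groups. Within each list, p-values were also adjusted over the list alone, without a correction across the 31 lists.

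The lists, tests, alternatives and the rule for naming genes were set before the data were examined, except where said. Counts of genes at least 2-fold apart between arrays other than the EGC, ESC and parental lines were added later. The rule takes the 8 genes with the largest rise and fall among those past the threshold, or the 6 highest and lowest differences where none passed or no test was run. It adds up to 4 members of each list outside the range, 19 fixed germ cell and pluripotency genes, the members of the list matching each day 2 addition, and the forced gene on all EBRTcH3 arrays. Probes named only by an accession or clone were passed over.

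The fits were tested on simulated data with 200 changed genes. Of changes of 4 on the log2 scale, the trend, the test of PGCs against lines and the Blimp-1 test recovered 0 percent. The single day 2 additions recovered 89.4 to 97.0 percent, 2i with A83-01 recovered 80.3 percent and the other constructs 25.8 to 53.0 percent. Of changes of 2, the single day 2 additions recovered 10.45 to 17.91 percent and every other fit at most 2.985 percent. Of changes of 1, the day 2 fits recovered 0 percent, so 0 calls there say little about differences of this size. In the real arrays, limma called 0 of 18671 genes for 4OHT, although 8740 had an unadjusted p under 0.05. The recovery in simulated data may therefore not carry over to the real day 2 arrays. There, 0 calls do not exclude changes of 4 either. Between 0 and 9 unchanged genes passed in a fit. Alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' table, no filter or a filter on every array, the mean of all probes, an intensity trend in eBayes, other slide terms, other time scales and leaving out each array. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.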

Results

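The first comparison followed PGCs from the embryo into culture. On the array of uncultured PGCs, Pou5f1 was at a level of 3.98, Nanog at 3.12 and Sox2 at 1.92, and germ cell genes were high: Dppa3 at 5.88, Tfap2c at 3.94, Dnd1 at 4.04 and Nanos3 at 1.60. After 1 day with bFGF all 10 BMP targets were at least 2-fold lower, with a median log2 difference of -3.35. Id1 stood at 5.04 in PGCs and 0.98 at day 1, Id2 at 5.75 and 2.32, and Id3 at 6.10 and 2.19; these genes encode dominant-negative helix-loop-helix proteins. Sterol and fatty acid synthesis was lower as well, with 16 of 22 genes at least 2-fold down. Sqle went from 4.32 to 2.61 and Hmgcs1 from 5.41 to 3.50. Nanos3 was at -0.45 and Dnd1 at 1.69 by then, while Pou5f1 was still at 3.36. All 11 mesenchymal transition genes and 9 of 12 fibroblast markers were at least 2-fold higher at day 1. Col1a1 stood at -2.50 in PGCs and 3.47 at day 1, and Dcn at 0.06 and 5.21. Between these arrays 8268 of 15589 genes differed at least 2-fold, 2664 higher and 5604 lower at day 1. The median of all genes was -0.48, the arrays lie on different slides, and with 1 array each the difference has no replicate check. The PGC array is also one of the dimmer arrays, and a part of brightness in this difference was not tested.

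Between day 1 and day 2, when 2i and A83-01 were added, TGF-beta and activin targets were lower (median -1.16, 9 of 16 at least 2-fold down), and so were ERK-responsive genes (-0.74, 7 of 15). Lefty1, a Nodal antagonist and activin target, went from -1.28 to -3.70. Fibroblast markers were higher still at day 2, by a median of 0.96. By list medians the germ cell program was lowest at day 3: 12 of 15 PGC markers and 17 of 24 later germline genes were at least 2-fold below day 2, with medians of -1.54 and -1.65. Prdm1, which encodes the PGC regulator Blimp-1, went from -0.98 to -3.69, Dppa3 from 4.76 to 2.36, Dnd1 from 1.37 to -1.68 and the RNA helicase gene Ddx4 from 1.06 to -1.39. Fibroblast markers were lower at day 3 too, 8 of 11 at least 2-fold. ERK-responsive genes were higher by a median of 0.71. Dnmt3l, a cofactor of de novo DNA methylation, stood at -3.62 at day 2 and 1.90 at day 3. At least 2-fold differences were seen for 1470 of 16397 genes from day 1 to day 2 and 1547 of 16266 from day 2 to day 3, with no replicate check.

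The pluripotency network was higher at day 6. Of its 28 naive genes, 24 were at least 2-fold above day 3, with a median of 1.76: Pou5f1 went from 2.08 to 3.88, Nanog from 1.97 to 4.04, Sox2 from 0.52 to 2.37 and Zfp42 from 3.51 to 5.22. Primed epiblast genes (median 2.44, 10 of 13), Wnt targets (2.42, 10 of 15) and imprinted genes (1.65, 13 of 21) were also higher. Later germline genes came back, 20 of 25 at least 2-fold, among them Mael, which went from -0.37 to 2.62. Dnd1 at -1.02, Nanos3 at -1.84 and Prdm1 at -3.76 stayed below their levels in PGCs. At day 10 the naive genes were higher again by a median of 0.89 and the primed genes by 1.00. Immediate early and heat shock genes were lower by 2.07, with Fos at 3.47 on day 6 and -0.21 on day 10 and Egr1 at 4.21 and 0.66. Fibroblast markers were lower by 0.73, and in the EGC line 11 of 12 were at least 2-fold below day 10; Dcn stood at 3.76 on day 10 and -1.26 in the EGC line. Hox genes were 1.59 lower in the EGC line, and all 17 glycolysis genes were higher than at day 10 (median 0.93). The numbers of genes at least 2-fold apart were 3325 from day 3 to day 6, 2993 from day 6 to day 10 and 2160 from day 10 to the EGC line. Only day 3 and day 6 share a slide, and none of these differences has a replicate check.

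**Figure D1:**
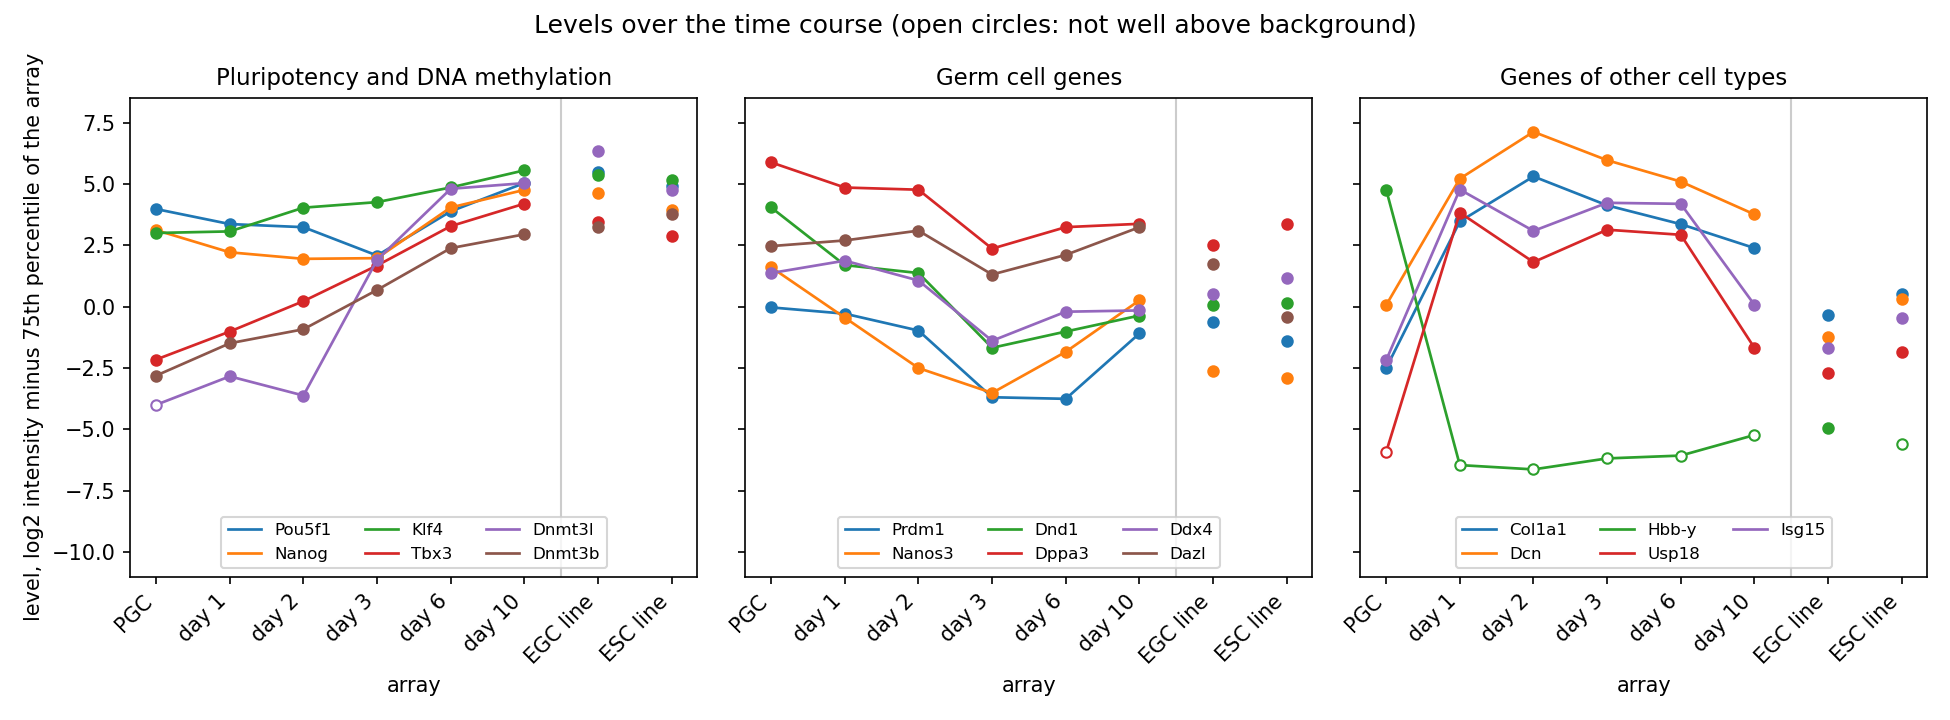
Levels (log2 intensity minus the 75th percentile of the array) of pluripotency, germ cell and other genes on the 6 time course arrays, joined by lines, and in the EGC and ESC lines, with 1 point per array and open circles for genes not well above background. Dnmt3l goes from -4.00 in PGCs to 5.03 at day 10, Prdm1 is lowest at day 6 (-3.76), and Dcn peaks at day 2 (7.12).

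Over the 6 arrays of the course, 10 of 18663 genes changed along log time. Tbx3, a transcription factor of the naive network, rose by 1.96 per log2 unit of time (SE 0.17), Galnt6 by 1.93 (SE 0.16), the water and glycerol channel gene Aqp3 by 1.62 (SE 0.15) and the Krüppel-like factor gene Klf9 by 1.43 (SE 0.13). Each was higher at every later array. Keg1 fell by 2.62, the trefoil factor gene Tff2 by 2.45, Slc23a3 by 2.02, B3galt5 by 1.61, Chst13 by 1.59 and the aminopeptidase gene Enpep by 1.49 per unit. These 6 were lower at every later array, except Keg1 between day 2 (-3.23) and day 3 (-3.19). Of the naive genes, 6 of 28 passed when adjusted over the list alone, all rising (Klf4, Klf5, Tbx3, Tdgf1, Eras and Dnmt3l), against 1 over all genes. Of the DNA methylation genes 4 of 12 rose when adjusted over the list alone (Dnmt3b, Dnmt3l, Uhrf1 and Tet2), of the primed genes 5 of 14, and 3 of 13 epithelial genes fell (Cldn6, Cldn7 and Crb3), against 0 in each list over all genes. Genes of other cell types changed as well: 9 of 11 blood cell genes (median slope -0.53) and 13 of 15 gonadal somatic genes (-0.37) fell. Fibroblast markers rose in 11 of 12 cases, with a median slope of 0.55, the same as that of the naive genes (0.55). Of the p53 targets 15 of 16 rose (0.40). The test was limma's, and all 10 genes had an adjusted p of 0.0498, while 2306 genes had an unadjusted p under 0.05. No gene passed when any 1 of the 6 arrays was left out, with linear or ranked days, with slide in the model, with normexp or with the authors' table; medium and slide change along with day.

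Uncultured PGCs were next set against the 3 pluripotent lines. All 10 BMP targets were higher in PGCs, 9 of them at least 2-fold, with a median of 3.85; Id3 was 31.3-fold and Id2 25.6-fold higher. Hox genes were higher in 19 of 22 cases (median 2.52), with Hoxd4 at least 84.0-fold and Hoxb7 at least 91.3-fold above the lines. The germ cell genes Nanos3 (log2 difference 4.27, SE 0.71), Dnd1 (3.88, SE 0.69) and Dppa3 (2.51, SE 0.92) were higher. The de novo methylation genes were lower: Dnmt3b by a log2 difference of -5.93 (SE 0.86) and Dnmt3l at least 850.1-fold. Of 28 naive genes, 21 were at least 2-fold lower, including Tbx3 (-5.67, SE 0.84) and Tdgf1 (-5.07, SE 0.70), and 11 of 13 primed genes were; Pou5f1 (-1.62) and Nanog (-1.47) differed less. All 17 glycolysis genes were lower (median -1.34), Hk2 by -4.35. Transcripts of other cell types moved with these groups. The embryonic globin gene Hbb-y stood at 4.77 in PGCs and was well above background in 1 of the 3 lines, and 8 of 10 blood cell genes and 10 of 15 gonadal somatic genes were at least 2-fold higher. Immediate early and heat shock genes were higher as well, 10 of 14 at least 2-fold, with Fos at 4.22 in PGCs and a mean of -1.38 in the lines and Jun at 3.22 and -2.21.

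With limma, 0 of 18515 genes passed between PGCs and lines; 1830 had an unadjusted p under 0.05 and the smallest adjusted p was 0.144. Adjusted over the list alone, 6 of 10 BMP targets, 9 of 22 Hox genes, 4 of 12 DNA methylation genes, 8 of 13 primed genes, 6 of 28 naive genes, 7 of 10 blood cell genes, 4 of 15 gonadal somatic genes, 4 of 15 PGC markers and 6 of 14 immediate early and heat shock genes passed, and 0 of 17 glycolysis genes. The BMP and Hox genes that passed were all higher in PGCs, the methylation, primed and naive genes all lower. Of those that passed, 1 blood cell gene (Laptm5), 1 PGC marker (Lin28a) and 1 heat shock gene (Hspb1) were lower in PGCs, and the others of these 3 lists higher. The count changed when the ESC or the EGC array was left out, but such fits have 1 residual degree of freedom. The prior degrees of freedom of eBayes, which weigh the spread shared across genes, then went from 3.4 to 223 without the ESC array. Without the parental array they were 2.5. The change in the count therefore cannot be put down to the spread of particular lines.

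The EGC line and the ESC line were then compared. The core network stood close together: log2 differences (EGC minus ESC) were 0.57 for Pou5f1, 0.70 for Nanog, 0.40 for Sox2 and 0.23 for Klf4, and 25 of 28 naive genes were higher in EGCs by a median of 0.58. Later germline genes were higher, 16 of 25 at least 2-fold, with Mael 7.94-fold, Tex101 11.6-fold and Dazl, an RNA-binding protein gene of germ cells, 4.52-fold higher. All 15 measured endoderm genes were higher, 11 at least 2-fold; Gata6 was 12.5-fold and Cubn 25.8-fold above ESCs. All 16 p53 targets were higher (median 1.09). All 13 epithelial genes were lower (median -1.11), with Cdh1, the E-cadherin gene, 4.69-fold and Cldn6 4.36-fold below ESCs. The imprinted growth factor gene Igf2 was 57.9-fold lower. Among the highest differences, Aqp8 was at least 298-fold and Srgn 114-fold higher in EGCs. Syt10 was 380-fold higher in EGCs, but parental EBRTcH3 ESCs also had it at 7.45, against -2.23 in the ESC line.

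In all, 3385 of 17408 genes were at least 2-fold apart, 2137 higher and 1248 lower in EGCs, with 803 of these as bounds. As a yardstick, parental EBRTcH3 ESCs and the ESC line were at least 2-fold apart for 7623 of 15096 genes, but the parental array is one of the dimmest. Levels of the ESC line correlated at 0.860 with this array, at 0.950 with GFP cells of the same line and at 0.964 with the EGC line. The yardstick may therefore reflect this array more than differences between ESC cultures. There is no replicate check, and the count was 1738 with normexp and 5746 without the filter on dim probes.

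At day 2, single additions to bFGF were compared with bFGF alone. With the MEK inhibitor, fibroblast markers were lower than with bFGF (median -0.97, 6 of 12 at least 2-fold): Col3a1 was 3.94-fold and Postn 5.60-fold lower. Epithelial genes were lower (median -0.48), among them Cldn4, Cldn6 and Krt8, and 22 of 28 naive genes were higher by a median of 0.28; Nanog stood at 1.82 with bFGF and 2.40 with the inhibitor. Feedback genes of the ERK pathway were not lower than in bFGF alone: Dusp6 stood at 3.68 and 4.19, Spry4 at -2.11 and -1.54, and Etv4 at 0.21 and 1.11. In the additive model, where the inhibitor's term also draws on the arrays with 2i and A83-01, 13 of 15 ERK-responsive genes were lower, with a median of -0.51. The sign also differed between the 2 contrasts for PGC markers (-0.25 against bFGF, 0.40 in the model) and fibroblast markers (-0.97 and 0.44). Of 18671 genes, 0 passed by limma and 601 had an unadjusted p under 0.05. Adjusted over the list alone, 4 of 13 epithelial genes passed, all lower (Cldn4, Cldn6, Ocln and Krt8), and 0 ERK-responsive genes, naive genes, PGC markers or fibroblast markers. The bFGF array lies on another slide, and the count was 710 with slide in place of 4OHT in the model.

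With the GSK inhibitor, epithelial genes were higher than with bFGF (median 1.58, 9 of 13 at least 2-fold): Krt8 was 4.02-fold, Spint2 4.59-fold and Cldn6 3.61-fold higher. Fibroblast markers were lower (median -2.38, 8 of 12), with Col3a1 15.9-fold and Dcn 6.76-fold lower. Naive genes were higher by a median of 0.61, 22 of 28, including Nr0b1 (4.18-fold) and Dnmt3l (5.16-fold), whereas Klf4 was 2.36-fold lower. Among Wnt targets, Sp5 was 4.96-fold higher and Lgr5 at least 3.89-fold higher, while Axin2 (-0.27) and Lef1 (0.15) lay close to bFGF; the list median was 0.52 in the model and above the range of random lists. In the model 14 of 15 PGC markers were also higher, by a median of 0.58; in the plain difference their median (-0.11) and mean (0.02) differed in sign. By limma 0 of 18671 genes passed and 879 had an unadjusted p under 0.05. When adjusted over the list alone, 5 of 13 epithelial genes (Cldn3, Cldn4, Cldn6, Ocln and Krt8) and 1 of 14 Wnt targets (Sp8) passed, all higher, and 0 naive genes, PGC markers or fibroblast markers. The count was 616 with slide in place of 4OHT in the model.

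With A83-01, germ cell and pluripotency genes were lower than with bFGF. Of 15 PGC markers 11 were at least 2-fold lower (median -1.63), with Prdm1 6.67-fold, Kit, the receptor for stem cell factor, 5.08-fold and Dppa3 4.26-fold lower. Later germline genes were lower in 22 of 25 cases (median -1.59), Mael 3.85-fold and Ddx4 3.60-fold. Pou5f1 (log2 difference -1.50), Nanog (-1.06), Sox2 (-0.94) and Esrrb (-1.34) were lower, and 11 of 28 naive genes were at least 2-fold down. Targets of the inhibited pathway were lower: Lefty1 at least 16.8-fold, Tgfbi 2.73-fold and Pmepa1 2.90-fold. ERK-responsive genes were higher by a median of 0.62, with Dusp6 2.67-fold, and trophectoderm genes by 1.02. Immediate early and heat shock genes were higher in 13 of 14 cases (median 0.36), above the range of random lists. Fibroblast markers were lower (median -1.40, 8 of 12 at least 2-fold). The medians of PGC markers (-0.94), later germline genes (-0.90), naive genes (-0.90) and TGF-beta and activin targets (-0.43) were negative in the additive model as well. That term draws on the same A83-01 array, so the shared sign is not independent. With 2i and A83-01 against bFGF, the medians were 0.17, 0.12, 0.01 and -0.68 in the same order. The other lists held less well in the model. Fibroblast markers changed sign there, with a median of 0.15 and 9 of 12 higher. ERK-responsive genes had a median of 0.08 and trophectoderm genes of 0.07. These lists lay within the range of random lists in the model, while immediate early and heat shock genes (0.70) stayed above it. Levels on the A83-01 array correlated more with day 3 (0.987) than with day 2 bFGF (0.978). With limma 0 of 18671 genes passed and 694 had an unadjusted p under 0.05. Adjusted over the list alone, 1 of 16 TGF-beta and activin targets, Pmepa1, passed and was lower, and 0 PGC markers or later germline, naive, ERK-responsive, trophectoderm or fibroblast genes. The count was 609 with slide in place of 4OHT in the model.

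The combination of 2i and A83-01 differed from bFGF less than each single addition did, and here both arrays share a slide. All 15 ERK-responsive genes were lower (median -0.46): Etv4 5.22-fold, Spry4 2.85-fold, Fosl1 2.74-fold and Dusp6 2.10-fold. TGF-beta and activin targets were lower in 13 of 16 cases (median -0.68), Lefty1 4.02-fold and Ltbp2, which encodes a matrix protein that binds microfibrils, 3.41-fold. The Wnt targets Sp5 (log2 difference 1.08) and Axin2 (0.80) were higher, while the median of the Wnt list was 0.01. Naive genes had a median of 0.01 and a mean of -0.16, with Pou5f1 at -0.07 and Zfp42 at -0.05. PGC markers were 0.17 higher, and fibroblast markers had a median of 0.01 and a mean of -0.31. At least 2-fold differences were seen for 636 of 16208 genes, against 1691 of 17206 with the MEK inhibitor, 3125 of 16732 with the GSK inhibitor and 2281 of 17371 with A83-01, which lie on a slide apart from bFGF. The model's sum of the 3 terms gave 0 of 18671 genes by limma and 459 with an unadjusted p under 0.05. Adjusted over the list alone, 1 of 16 TGF-beta and activin targets (Pmepa1, lower) passed, and 0 ERK-responsive genes, Wnt targets, naive genes, PGC markers or fibroblast markers. The count was 301 with only the 4 arrays that cross 4OHT with the combination, and 470 with slide in place of 4OHT.

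**Figure D2:**
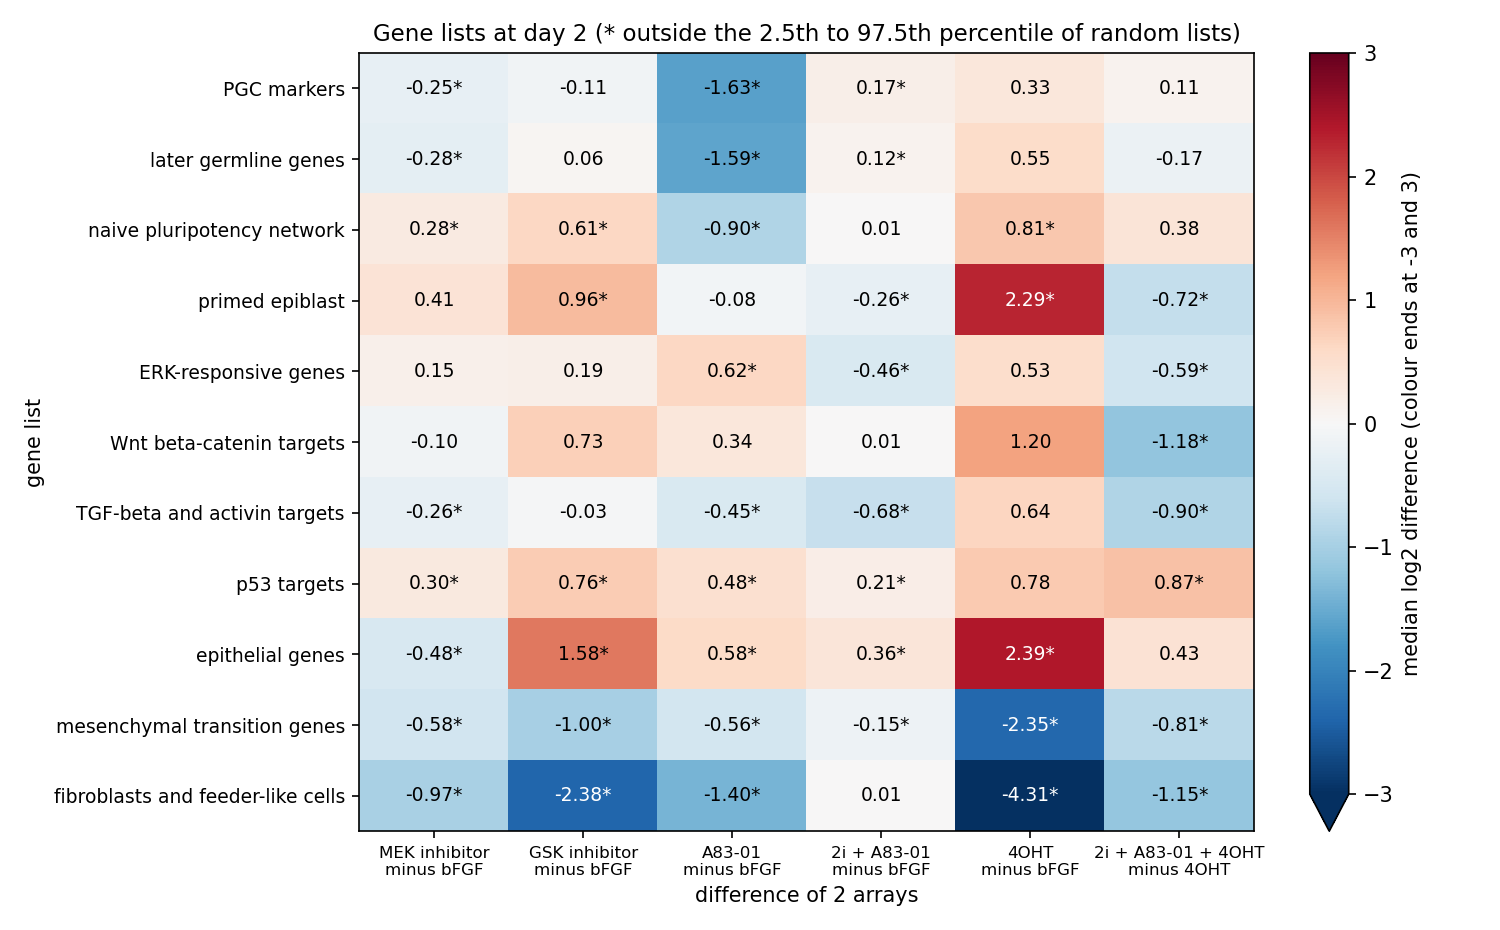
Median log2 difference of 11 gene lists in 6 differences between day 2 arrays, as colour and printed value, with an asterisk where the median lies outside the range of random lists. PGC markers are lowest with A83-01 (-1.63) and fibroblast markers with 4OHT (-4.31).

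The widest differences at day 2 came with 4OHT. Fibroblast and mesenchymal genes were lower: Col3a1 was 92.9-fold, Dcn 40.3-fold and Zeb2 11.1-fold lower than with bFGF, and 10 of 12 fibroblast markers (median -4.31) and 9 of 11 mesenchymal transition genes (-2.35) were at least 2-fold lower. Epithelial genes were higher, 10 of 13 at least 2-fold (median 2.39), with Krt8 6.38-fold and Spint2 7.18-fold. Trophectoderm genes were higher too, 9 of 13 at least 2-fold (median 2.38). Immediate early and heat shock genes were lower in 10 of 14 cases (median -0.52). Naive genes were higher by a median of 0.81: Klf2 6.46-fold, Nr0b1 6.84-fold and Dnmt3l 12.8-fold, but Klf4 was 3.75-fold lower. Among germ cell genes, Nanos3 stood at -1.38 with bFGF and 0.76 with 4OHT, and Prdm1 at -1.14 and -2.67. Sterol and fatty acid synthesis was higher in 18 of 22 genes (median 0.81), including Idi1 (4.16-fold), an isomerase gene of the isoprenoid pathway; in the model the list median was 0.71, within the range of random lists. FOXO targets, which AKT is known to restrain, did not move together: Ccng2 had a log2 difference of 1.23 and Bcl6 of -2.07, and the list lay within the range of random lists, as did the p53 targets (Ccng1 2.09-fold higher). The neuropeptide genes Npy and Pnoc were 61.9-fold and 53.5-fold higher. These differences sit on a median of all genes of 0.36 (0.58 in the model). In all, 6340 of 15838 genes were at least 2-fold apart, 4429 higher and 1911 lower.

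In the model with 4OHT, limma called 0 of 18671 genes, but 8740 had an unadjusted p under 0.05, the smallest adjusted p was 0.0524 and 8373 genes had an adjusted p under 0.1. Col1a1 had a coefficient of -5.45 (SE 1.00), Dcn -4.93 (SE 0.98), Pnoc 5.41 (SE 0.51) and Cldn4 2.63 (SE 0.25). Adjusted over the list alone, 11 of 13 epithelial genes passed, all higher, 10 of 12 fibroblast markers, 9 of them lower, 7 of 11 mesenchymal transition genes, all lower, 9 of 28 naive genes and 11 of 22 sterol and fatty acid genes, 8 of each higher, 4 of 15 FOXO targets and 0 p53 targets. Both 4OHT arrays fill a slide that holds no other array, so 4OHT and slide cannot be separated. The count was 8380 with normexp, 15352 without the filter on dim probes, 6012 with the filter on every array, 4174 with the mean of probes, 7494 with an intensity trend and 8512 with the 4 arrays that cross 4OHT with the combination, and leaving out single arrays gave 0 to 9619.

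The effect of 2i and A83-01 was compared between cultures without and with 4OHT. With 4OHT, the combination again went with lower TGF-beta and activin targets (median -0.90, 7 of 16 at least 2-fold) and lower ERK-responsive genes (-0.59): Egr1 stood at 2.29 with 4OHT and -0.36 with all additions, and Etv4 at 1.94 and 1.00. The p53 targets were higher by a median of 0.87 (7 of 16 at least 2-fold), with Ccng1 at 3.85 and 5.04, against a median of 0.21 without 4OHT. Wnt targets were lower by -1.18 and fibroblast markers by -1.15, where both had a median of 0.01 without 4OHT. Nanog stood at 2.47 and 4.02, Pou5f1 at 4.05 and 4.91, Dppa3 at 4.48 and 5.59, and the growth factor gene Igf1 at -2.94 and 1.95. Over 17234 genes the effects without and with 4OHT had a Pearson correlation of 0.0911 and a Spearman correlation of 0.194, and of 965 genes at least 2-fold apart without 4OHT, 55.2 percent went the same way with it. The 4OHT effects without and with the combination correlated at 0.798, but both set the 4OHT slide against the slide of bFGF. A shift between these slides would enter both, so this value is not an independent repeat of a 4OHT effect. The first Pearson value was 0.326 with genes well above background on every array and 0.248 with normexp. Under these settings the share going the same way was 78.2 percent of 142 genes and 64.0 percent of 264 genes. The differences within each correlation share no array, but there is no replicate check.

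Forced genes were then read on the 8 EBRTcH3 arrays. Nanos3 stood at 2.66 on the array labelled Nanos3 and at no more than -0.33 on the others. The other forced genes did not stand out: Dnd1 was at 1.43 on the array labelled Dnd and 1.92 on the array labelled Blimp-1, Ddx4 (Vasa) at 0.01 on the array labelled Vasa and 0.26 on the parental array, and Prdm1 (Blimp-1) at -1.38 on the array labelled Blimp-1 and -0.17 with GFP. Nanos2 was well above background on 0 arrays, and Prdm14 has no probe under its name. Whether the probes match the expressed constructs is not given in the sources used here. The parental array itself stood apart: in a test added after the data were seen, limma called 22 genes against its slide mates, 21 higher and 1 lower, and GFP cells and parental cells were at least 2-fold apart for 5287 of 14911 genes.

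On the array labelled Prdm14, two-cell-like genes were higher: Tcstv1 was 18.0-fold and Zscan4c at least 11.9-fold above the slide mates, and 5 of 7 members passed adjusted over the list alone, against 0 over all genes. Usp17la, which is not on the list, was at least 29.6-fold higher. Later germline genes were higher in 20 of 23 cases (median 0.85), and the meiotic cohesin gene Smc1b was at least 13.5-fold and the melanocyte gene Mlana 28.6-fold higher. Primed epiblast genes were lower in 12 of 14 cases (median -0.84), with Lefty1 14.1-fold, Lefty2 5.75-fold and Otx2 4.23-fold lower, and the Wnt receptor gene Fzd7 was 7.40-fold lower. Nanog (log2 difference 0.06) and Esrrb (-0.04) lay close to the slide mates. Endoderm genes had a median of 1.40, with Dab2 at least 6.64-fold higher. The slide mates include the parental array, and against it alone the median was 2.475. GFP cells were also above parental cells in this list (1.68), as were the arrays labelled Nanos2 (1.04) and Nanos3 (1.04), all outside the range of random lists. Those labelled Vasa (0.73) and Dnd (0.81) lay within it. Epithelial genes were lower by a median of -0.87, and against the parental array by -1.33; GFP cells were also lower than parental cells in this list (-1.19). By limma 0 of 18822 genes passed and 1177 had an unadjusted p under 0.05; adjusted over the list alone, 0 later germline, primed epiblast, endoderm or epithelial genes passed. The count was 61 with quantile normalization.

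On the array labelled Vasa, later germline genes were lower in 21 of 23 cases (median -0.74): Fkbp6 was 7.93-fold and Tdrd1 4.92-fold lower than on the slide mates, and Dppa3 7.04-fold lower. Two-cell-like genes were lower by a median of -2.37, with Tcstv1 5.18-fold; the slide mates include the array labelled Prdm14, where this list and the later germline genes were high. Against the parental array alone, later germline genes had a median of -0.35, within the range of random lists. Of DNA methylation genes 11 of 12 were higher (median 0.40), with Dnmt3b 2.10-fold, and ERK-responsive genes were higher by 0.45, with Spry2 2.42-fold. Pou5f1 (0.33), Nanog (-0.04) and Sox2 (0.14) lay close to the slide mates. The basement membrane gene Lama1 was at least 8.60-fold higher. Of 18822 genes, 0 passed by limma and 521 had an unadjusted p under 0.05; adjusted over the list alone, 1 of 23 later germline genes passed (Fkbp6, lower), and 0 DNA methylation, ERK-responsive or two-cell-like genes. The count was 23 with quantile normalization.

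On the array labelled Nanos2, the antiviral gene Oas1a was at least 25.9-fold and Pramel26 at least 17.2-fold higher than on the slide mates. Naive genes were higher in 23 of 28 cases (median 0.84), with Nanog (1.92, SE 1.01) and Tbx3 (1.74, SE 1.19), but the slide mates include the array labelled Nanos3, where they were low; against the parental array the list had a median of 0.00 and a mean of -0.06, within the range of random lists. Relative to parental cells, glycolysis genes were higher in 15 of 17 cases (median 0.71) and sterol and fatty acid genes in 20 of 22 (0.64). GFP cells were also above parental cells in both lists (0.29 and 0.18), outside the range of random lists. So were glycolysis genes on the arrays labelled Prdm14 (0.40), Vasa (0.37), Nanos3 (0.23) and Dnd (0.46). Sterol and fatty acid genes were so with Nanos3 (0.55) and Dnd (0.44) but not with Prdm14 (-0.14) or Vasa (0.00). Later germline genes were higher by a median of 0.71 against the slide mates, with Mael 3.25-fold and Rhox9 6.18-fold; against the parental array their median was 0.27, within the range of random lists. By limma 0 of 18822 genes passed, 544 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0543; adjusted over the list alone, 0 naive, glycolysis, sterol and fatty acid or later germline genes passed. The count was 55 with quantile normalization and 27 without the slide term.

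On the array labelled Nanos3, naive genes were lower in 26 of 28 cases against the slide mates, with a median of -1.22: Nr0b1 by a log2 difference of -3.52 (SE 0.68), Tbx3 by -3.01 (SE 0.71), Nanog by -2.93 (SE 0.52), Zfp42 by -2.70 (SE 0.45) and Esrrb by -2.39 (SE 0.41). Pou5f1 (-0.31, SE 0.46) differed less. Trophectoderm genes were higher (median 2.22, 10 of 13): the trophectoderm regulator gene Cdx2 was at least 34.6-fold and Krt8 17.8-fold above the slide mates, and Gata3 at least 8.11-fold. Wnt targets were higher in 12 of 15 cases (median 1.03), with Sp5 17.4-fold and T, the Brachyury gene, at least 11.4-fold. The contractile genes Cnn1 (42.7-fold), Acta1 (33.0-fold) and Tagln (20.2-fold) were higher, and 7 of 9 fibroblast markers were higher (median 1.35). Mesoderm genes had a median of 0.47 and imprinted genes of 0.49. The X-linked gene Rhox5 was 24.0-fold and the oocyte gene Khdc3 20.9-fold lower, and 26 of 30 mitotic cell cycle genes were lower (median -0.48).

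With limma, 0 of 18822 genes passed on the array labelled Nanos3 and 1728 had an unadjusted p under 0.05, with 0.185 as the smallest adjusted p. When adjusted over the list alone, 13 of 28 naive genes passed, all lower, 5 of 15 Wnt targets, 4 of them higher, 3 of 16 TGF-beta and activin targets, all higher, 1 of 13 trophectoderm genes, Cdx2, and 2 of 15 mesoderm genes, 1 higher and 1 lower, but 0 fibroblast, imprinted or mitotic cell cycle genes. Against the parental array naive genes had a median of -1.26, and 6270 of 14921 genes were at least 2-fold apart, against 5287 of 14911 for GFP and parental cells. The count was 53 without the slide term and 8 with quantile normalization.

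**Figure D3:**
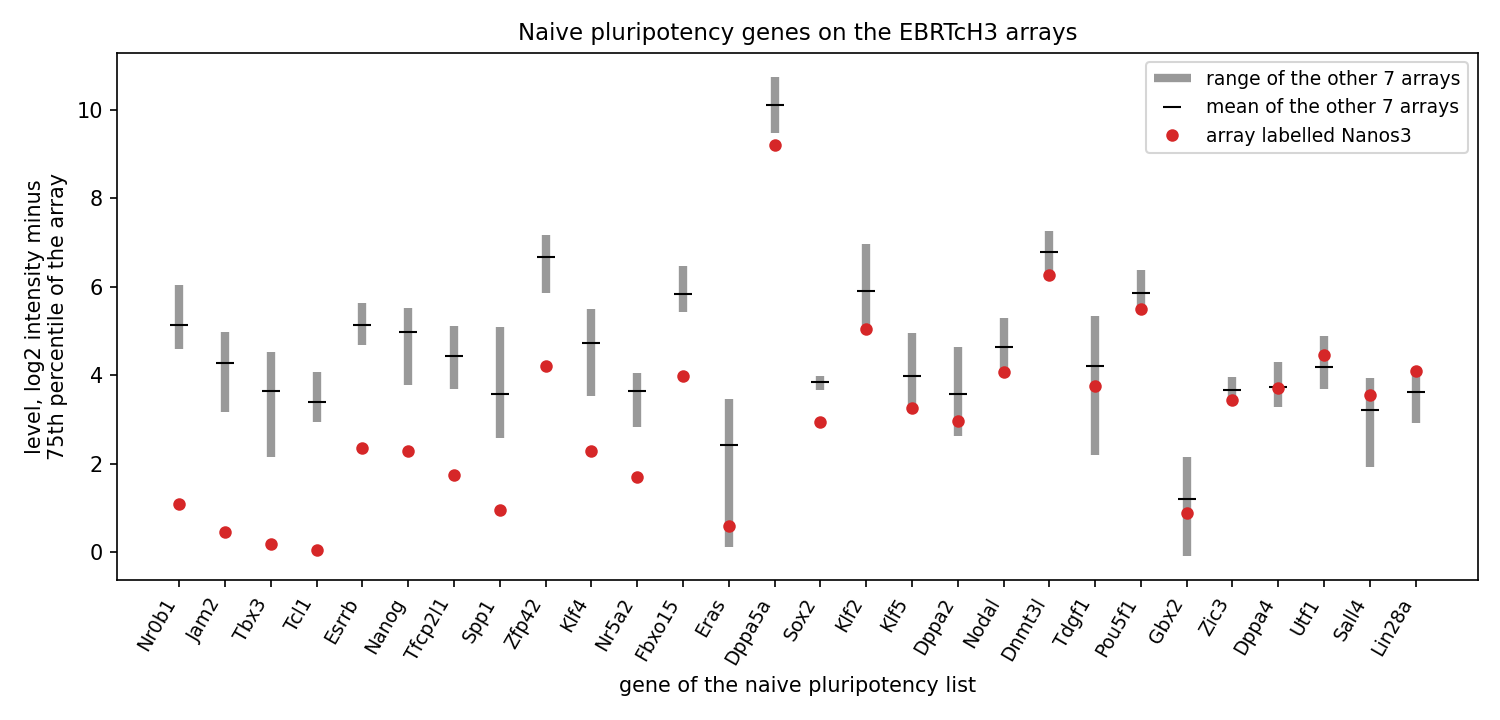
Levels of the 28 naive pluripotency genes on the array labelled Nanos3 (points) beside the range (bars) and mean (dashes) of the other 7 EBRTcH3 arrays, in log2 intensity minus the 75th percentile of the array. For 17 of the 28 genes the point lies below every other array.

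On the array labelled Dnd, 2 probes passed, A_52_P724652 at least 75.04-fold and B230303O12Rik at least 50.45-fold above the slide mates, both with an adjusted p of 0.0387 that rests on background values of the other arrays; the naming rule leaves such probes out, and they were chosen after their values were seen. They stood at 1.39 and 0.82 on this array and were well above background on 0 of the other 7, though B230303O12Rik was so in the ESC and EGC lines. Naive genes were higher than on the slide mates in 25 of 28 cases (median 0.80), with Klf4 3.06-fold and Esrrb 2.46-fold, but these mates again include the array labelled Nanos3; against the parental array 17 of 28 were lower (median -0.26), within the range of random lists. Later germline genes were lower than on the slide mates (median -0.69), Mael 3.22-fold and Tdrd1 2.73-fold, but these include the array labelled Nanos2, where they were high, and against the parental array (-0.49) the list lay within the range of random lists. Trophectoderm genes were lower against both the slide mates (-0.81) and the parental array (-1.27). Against the parental array DNA methylation genes were higher by 1.07, as they were in GFP cells (1.35). By limma 421 of 18822 genes had an unadjusted p under 0.05; adjusted over the list alone, 0 naive, later germline, trophectoderm or DNA methylation genes passed. The 2 calls ended with normexp, with the filter on every array, with an intensity trend and without the slide of Blimp-1 and GFP, and leaving out any 1 other array left 0 or 1 of them. The count was 94 with quantile normalization and 64 without the slide term.

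On the array labelled Blimp-1, trophectoderm genes were higher than with GFP on the same slide, 9 of 12 at least 2-fold (median 2.45): Krt7 was 24.8-fold, Hand1 11.4-fold and Cdx2 9.42-fold higher, and Plac1 at least 7.77-fold. Gata2 was 18.8-fold, the secretin gene Sct 26.1-fold and Mogat2 31.6-fold higher. All 11 measured Hox genes were higher (median 1.17), and G1 cyclins and CDK inhibitors had a median of 0.76, with Cdkn1c 3.50-fold and Cdkn2c 2.46-fold. Naive genes were lower in 21 of 28 cases (median -0.28), including Tbx3 (log2 difference -1.81), Klf4 (-1.40) and Nanog (-1.03), while Pou5f1 (-0.29) and Sox2 (-0.17) differed less and Klf2 was 2.08-fold higher. Among germ cell genes, Nanos3 was 7.27-fold and Dppa3 3.48-fold higher. DNA methylation genes were lower by a median of -0.45, with Dnmt3b 2.35-fold. By limma 0 of 18822 genes passed and 899 had an unadjusted p under 0.05; adjusted over the list alone, 2 of 15 Hox genes passed (Hoxa2 and Hoxd4, higher), and 0 trophectoderm, naive, DNA methylation or G1 genes. The array is the dimmer of the 2, with a 75th percentile at an intensity of 195 against 408 with GFP. Across 11343 genes the difference correlated at 0.28 with that of the dim parental array minus the brighter Prdm14 array. The count was 151 with quantile normalization and 154 without the slide term.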

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

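The tests of fibroblast-like cells with 4OHT, of a lower share of undifferentiated cells and of a mislabelled array for Nanos3 were chosen after the results were seen; the others in this part were set before, but the condition on abundant transcripts in the tests of red blood cells and liver cells was added after their values were seen. Of 122 genes of signalling pathways, germ cells and pluripotency well above background on the 4 arrays, 1 moved at least 2-fold in opposite directions with 2i and A83-01: Tdgf1, a Nodal co-receptor gene, had a log2 difference of -1.004 without 4OHT and 1.0 with it. This difference between the backgrounds was not tested.

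The 4OHT array differed widely from bFGF, with 6340 genes at least 2-fold apart, and both 4OHT arrays are also dim and alone on their slide. Part of the pattern was also seen on an array that saw no 4OHT and lies on another slide. Levels with 4OHT correlated at 0.976 with those of the GSK inhibitor array, which saw no 4OHT. With those of the other 4OHT array they correlated at 0.971. Against bFGF, the GSK inhibitor array also had lower fibroblast markers (median -2.38) and higher epithelial genes (1.58). Fibroblast markers were lower with the MEK inhibitor (-0.97) and A83-01 (-1.40) too, while epithelial genes were lower with the first (-0.48) and higher with the second (0.58). All of these differences subtract the same bFGF array, which lies on another slide. A shift of that array or slide would enter each of them, so they cannot separate 4OHT from slide. Across 11343 genes well above background on all 22 arrays, the 4OHT difference correlated at 0.539 with the difference between dim and bright EBRTcH3 arrays that saw no 4OHT, so array brightness may account for part of the pattern; genes are not independent replicates. Of the fibroblast markers well above background without 4OHT, 83.3 percent were at least 2-fold lower with it and 90.9 percent in the presence of 2i and A83-01, although the cells were sorted on SSEA-1. This test repeats the values that prompted it, so it neither supports nor excludes fewer fibroblast-like cells in the sort. The slide held 0 arrays of other groups, so slide and scan cannot be told apart from 4OHT. An effect of AKT activation on the germ cells, which the design names, stays open and was not tested apart from these.

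Globins and genes of kidney tubule were higher in uncultured PGCs than at day 1, when 19 of 23 kidney markers were still well above background. For liver cells, 5 of 20 markers (25 percent, the limit set) were well above background and at least 2-fold above the lines, which by that limit would exclude them. Alb (-5.64), Apoa1 (-5.49) and Ttr (-5.59) were not well above background either. These transcripts were chosen after the values were seen, however. Afp, of the endoderm list, was well above background in PGCs (2.45) with a mean of -4.54 in the lines, so liver cells stay open. For red blood cells 4 of 16 erythroid markers were well above background and at least 2-fold above day 1, again 25 percent, and the rule as first written would exclude them. The added condition keeps them open, because the globins Hbb-y (4.77), Hbb-bh1 (3.94), Hba-a1 (3.57) and Hba-x (2.19) were high. Kidney tubule cells may contribute as well, with 65.2 percent of 23 markers well above background and at least 2-fold above the lines, between the limits of 25 and 75 percent. Any such cells would have to pass the SSEA-1 sort, and expression of these genes by PGCs in the embryo was not tested.

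Naive genes are low on the array labelled Nanos3 by uneven amounts. The standard deviation of their differences from the mean of the other 7 arrays was 1.352, against 0.443 to 0.790 on the other arrays. A lower share of undifferentiated cells stays open: it would lower all of these genes alike only if the other cells lack them, which no array measures, and trophectoderm genes (median 2.22) and 7 of 9 fibroblast markers were higher on this array. Scaling is argued against because the list median was at percentile 0.0 of random lists at most over 7 settings. A mislabelled array is argued against because Nanos3 on this array was 2.988 above the highest of the other 7. An effect of forced Nanos3 on the naive network, which the design names, and differences between single cultures stay open as well.

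For the time trend, 1 of 100 orders of the 6 arrays drawn from 720, the real one, gave as many as 10 genes, and the highest other order gave 0. By the limit of 5 percent set before, this would exclude chance in the order for this count. Calls were hardly within reach of any order, however: 99 of the 100 gave 0 genes, and the fit recovered 0 percent of simulated changes of 4. The count therefore rests on little, and chance is not excluded for the trend. All 10 genes lie just under the threshold, at an adjusted p of 0.0498, and 0 passed when any 1 array was left out. The number of genes with an unadjusted p under 0.05, 2306, was reached by 15 of the 100 orders, with 5676 in the highest other, so that larger number is not particular to the order in time.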

How the results depend on the processing

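The comparison of the EGC line with parental EBRTcH3 ESCs in place of the ESC line was chosen after the data were seen; all other alternatives were set before. Replicates could not be paired because each group has 1 array, but fits with slide as a block are among the alternatives. Of 133 values of the counts and the correlation under settings other than leaving out an array, 79 were within 1.5 times and 54 were not. Where not said otherwise, the cause was not tested. The trend count of 10 was 21 with quantile normalization, 37 without the filter on dim probes, 16 with the filter on every array and 38 with an intensity trend in eBayes, sharing 10, 10, 3 and 9 genes with the 10, and it was 0 with normexp, the authors' table, linear days, ranked days and slide as a fixed or random block. The 10 genes kept their direction under every setting run. For PGCs against the lines the count of 0 was 58 with normexp, 81 without the filter and 24 with an intensity trend. With normexp the day 2 counts were 21 (MEK inhibitor), 10 (GSK inhibitor), 9 (A83-01), 8380 (4OHT) and 3 (2i with A83-01). With slide in place of 4OHT they were 710, 616, 609 and, for the combination, 470. With an intensity trend the MEK inhibitor had 1 gene. With 4OHT the count was 15352 without the filter, 6012 with the filter on every array, 4174 with the mean of probes, 7494 with an intensity trend and 8512 with the 4 crossed arrays, where the combination had 301. With quantile normalization the constructs had 61 (Prdm14), 23 (Vasa), 55 (Nanos2), 8 (Nanos3), 94 (Dnd) and 151 (Blimp-1) genes, and without the slide term 3 (Prdm14), 27 (Nanos2), 53 (Nanos3), 64 (Dnd) and 154 (Blimp-1). Normexp gave 1 gene for Prdm14, 2 for Nanos3 and 0 for Dnd, an intensity trend 1 for Nanos3 and 0 for Dnd, and the filter on every array 0 for Dnd, whose probes it leaves out. EGCs and ESCs were apart for 1738 genes with normexp, 5746 without the filter, 751 at 4-fold and 6895 with parental EBRTcH3 ESCs as the control. The correlation of the effects of 2i with A83-01 was 0.248 with normexp, 0.195 without the filter and 0.326 with the filter on every array.

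Leaving out 1 array gave 0 to 0 genes for the trend and for Prdm14, Vasa, Nanos2, Nanos3 and Blimp-1, and 0 to 1 for Dnd. It gave 0 to 566 for PGCs against the lines (566 without the ESC and 265 without the EGC array), 0 to 2012 for the MEK inhibitor, 0 to 1520 for the GSK inhibitor, 0 to 1558 for A83-01, 0 to 9619 for 4OHT and 0 to 462 for 2i with A83-01. At day 2 the arrays that moved these counts were those with bFGF alone, the MEK inhibitor, the GSK inhibitor and A83-01: without bFGF the counts were 74, 49, 54, 3664 and 6, and without the array with A83-01 they were 572, 1179, 1558, 9260 and 350, in the order above. Without the array with the GSK inhibitor they were 713, 1520, 1092, 9619 and 462, and without that with the MEK inhibitor 2012, 1354, 1042, 9487 and 420. Such fits have 1 residual degree of freedom, as do those with slide in place of 4OHT and with the 4 crossed arrays. Their counts also follow the prior degrees of freedom of eBayes. These were 2.5 in the main day 2 fit and 58.6 with slide in place of 4OHT, so the larger counts need not reflect larger differences. Not run, because the term cannot be estimated, were the 4 crossed arrays for the MEK inhibitor, GSK inhibitor and A83-01, slide as a block for 4OHT, and fits without the PGC array, a construct's own array or, for Blimp-1, the GFP array. Of 471 list medians outside the range of random lists, 311 were outside on the same side under all 6 settings. The medians that went to the other side were, with normexp, immediate early and heat shock genes with the MEK inhibitor (-0.11 to -0.008, from below to above the random lists), mesenchymal transition genes (-0.57 to 0.30) and fibroblast markers (-0.39 to 0.71) with the combination in the model, and, with the filter on every array, Hox genes in parental EBRTcH3 ESCs against the ESC line (-1.19 to 1.72). Of 18082 values under other settings of named genes not past the threshold, 288 passed it, 1436 were counted as moved and 16358 as the same. Where a test was run, the same means only that the threshold was still not passed, however far the value moved. The count of 16358 therefore does not show that the values were stable. Depth of signal limits most what can be said of 2i, A83-01 and 4OHT together and of the parental array, where 44.3 and 48.8 percent of probes were well above background.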

Other observations

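Interferon-stimulated genes formed a further group over the time course, read from a list of 24 genes that was chosen after the data were seen. Their median level was -5.00 in uncultured PGCs, 2.70 at day 1, 1.21 at day 2, 2.03 at day 3 and 2.13 at day 6. At day 10 it was -1.21, in the EGC line -1.58 and in the ESC line -2.03. Isg15, a ubiquitin-like protein gene, stood at -2.19 in PGCs, 4.77 at day 1 and 4.19 at day 6, and 0.07 at day 10. Ifit3 was not well above background in PGCs and stood at 3.94 at day 1, and the chemokine gene Ccl5 was at 4.76 on day 6 and -1.85 on day 10. The day 2 culture with bFGF alone had a median of 0.96, so the level was present without the inhibitors.

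Sex-linked genes differed between the samples. The Y-linked genes Ddx3y (-0.70) and Eif2s3y (1.71) and the X-linked Xist (1.47) were all well above background in uncultured PGCs. In the EGC line Ddx3y, Eif2s3y and Uba1y were not well above background and Xist was at -2.87. Among the EBRTcH3 arrays Ddx3y stood at 1.15 on the parental array, -3.13 on the array labelled Vasa and was not well above background on the array labelled Dnd. Hprt was between -3.09 and -5.06 on the EBRTcH3 arrays, not well above background on those labelled Vasa and Blimp-1, and at 5.32 in the ESC line. Stra8, a gene induced by retinoic acid in germ cells, was not well above background in PGCs and stood at 2.77 at day 1, 5.96 at day 10, 3.05 in the EGC line and 6.28 in the ESC line, but -1.65 in parental EBRTcH3 ESCs.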
